A study of Mus musculus with 8 samples.

How the data were processed

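RNA was sequenced from mouse astrocytes in 2 kinds of culture, MGS and conventional (CV), at day 5 and day 32, with 2 libraries in each of the 4 groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEB Ultra II directional kit. The series' design text names an Illumina NextSeq. Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0 and StringTie 1.3.4d were used, and the builds hg38 and mm10 are both named, without roles or order. The annotation release, any filters and the use of strand in the assignment of reads were not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain.

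The authors deposited 1 abundance file per library, with a value of coverage, FPKM and TPM for each gene row, per the file headers. The TPM values of each deposited library summed to 1000000 over its rows. FPKM, also per the file headers, was used only in an alternative. Coverage, the mean depth per base per the file headers, was used only for sequencing depth. A deposited table of the whole series gave TPM for 23401 genes. In every library its values equalled, within 1e-05 TPM, the last row of each gene ID, and 19 gene IDs whose symbols hold the letters alt were not in it. Between 132 and 157 gene IDs per library had several rows, so rows of 1 gene ID were summed from the library files. That gave 23420 gene IDs. The files listed 0 rows on the mitochondrial chromosome.

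Coordinates are those of the files, in mm10. Of the 23270 gene IDs with a single row, 21358 were matched by symbol and chromosome to the GRCm38 RefSeq annotation, and 99.86% of these overlapped the gene of that name. Transcript length and GC content came from the longest transcript of each gene in the GENCODE annotation of GRCm38, for 14787 of the 14904 genes tested (99.2%). Genes were matched to it by symbol or by RefSeq synonym.

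TPM keeps no depth. Coverage divided by FPKM was taken over gene rows with an FPKM above 1. It took 1 constant value in each library for 76.89% to 78.16% of these rows (relative tolerance 1e-05). That value gave the aligned bases per library, from 2.15 to 4.69 gigabases. The 10 most abundant genes held 6.17% to 10.49% of TPM. Read counts could not be recovered from these units, so no interval for counting error is given, and the spread between replicates is the error used. The replicates of a group correlated, across genes, with r = 0.996 (MGS day 5), 0.9904 (CV day 5), 0.9952 (MGS day 32) and 0.9799 (CV day 32), and 0 pairs of libraries held identical values. The median SD between replicates was 0.045, 0.14, 0.051 and 0.27 on the log2 scale in the same order.

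Genes with a TPM of at least 1 in at least 2 of the 8 libraries were tested. Values were taken as log2(TPM + 1), and limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 libraries in 1 model with 4 residual degrees of freedom. Empirical Bayes moderation used a trend of variance with mean, with a median of 3.3 prior degrees of freedom, and its tests were two-sided. All groups shared 1 estimate of the spread, although CV at day 32 was the noisiest group. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The 5 contrasts were MGS against CV at each day, day 32 against day 5 in each culture, and the culture by day interaction. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so no such test was made. The overlap of the calls of both days was tested with Fisher's exact test, one-sided for more shared genes than independent lists would give.

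The 34 gene lists were tested with camera in limma, with a preset correlation of 0.01 and, beside it, an estimated correlation, adjusted over the lists within a contrast. Of these 34 lists, 1 had no measured member. Medians of lists are given relative to the median of all genes tested unless stated otherwise. Of the results of these fixed lists, only microglia markers at day 32, within CV and in the interaction, and class I antigen presentation in the interaction were called with the estimated correlation.

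The design, the gene lists, the alternatives first listed and the rule for named genes were fixed before the data were examined. By that rule the text names up to 10 called genes with the largest rise and up to 10 with the largest fall in each comparison of the cultures, and up to 5 each way in the other 3 contrasts. Such genes needed a mean of at least 5 TPM in the higher group and, except in the interaction, no overlap between the libraries of the groups. Symbols that are only model names were left out, and the values of some genes that the rule names are not reported here. The rule also names up to 4 called members of each list by size of change, and 15 genes in any case. Other exceptions named beside small counts, such as Cd44, Ifit2, Klf6, Fhl2, Tpm2, Kdr, Cbs, Flnc, Kif11, Erap1, Hc, Cd55, Syn1 and Stmn2, were chosen after their values were seen, as were 3 additional gene lists and 2 lists, of leukocyte and of fibroblast genes on no fixed list, for tests of the closing section.

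The model was tested on simulated data in which all groups shared each gene's mean and residual spread, with independent noise. In the MGS group compared, 100 genes were changed 2-fold and 100 were changed 4-fold. For MGS against CV at day 5, over 14336 genes, the model recovered 59% of the 2-fold and 90% of the 4-fold changes, and 9 of 158 calls were unchanged genes. For day 32, over 14357 genes, it recovered 52% and 93%, and 8 of 153 calls were unchanged genes. In simulated lists for day 5, over 14344 genes, 0 of 30 unchanged lists were called. Those lists were drawn at random. The simulations therefore give no error rate under the unequal spread of the real groups, or for lists of correlated genes.

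Alternatives were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, FPKM, no variance trend, robust moderation, only the libraries compared, a replicate block in 2 forms, a 2-fold threshold, and leaving out each library in turn. Chosen after seeing the data were a correction for transcript length and GC content by natural splines (5 degrees of freedom each), the same with a replicate block, a variance weight per group, the series-wide table and a crossed replicate block. Data were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.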

Results

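Gene expression was measured by RNA sequencing in mouse astrocytes kept in 2 kinds of culture, a conventional culture (CV) and a culture that the labels call MGS without explaining the letters. The sample descriptions call the MGS libraries soft and the CV libraries hard. Each culture was sampled at day 5 and at day 32, and each of the 4 groups held 2 libraries, 8 in all. The design asks how astrocytes in MGS differ from conventionally cultured astrocytes. The aligned sequence behind each library, recovered from the abundance files, was 3.90 and 4.36 gigabases for MGS at day 5, 2.99 and 2.50 for CV at day 5, 4.69 and 4.61 for MGS at day 32, and 2.98 and 2.15 for CV at day 32. The CV libraries were therefore the shallower ones at both days. Between 12912 and 14441 gene IDs reached 1 TPM, the transcript abundance scaled to an equal total in every library, in a library. The SD of the log2 difference between the replicates of a group was 0.191 for MGS at day 5, 0.197 for MGS at day 32, 0.321 for CV at day 5 and 0.465 for CV at day 32. Values of the CV groups, at day 32 above all, rest on the noisier libraries. Of the 23420 gene IDs, 14904 were tested. Fold changes are on the scale of log2(TPM + 1), which understates the change of low genes, and are given with the standard error (SE) of the model. Levels are mean TPM ± SD (n = 2). The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

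At day 5 the astrocytes in MGS held far more Gfap, the intermediate filament protein of astrocytes, and far less Acta2, the smooth muscle actin, than astrocytes in CV. Gfap (chromosome 11, 102887336 to 102897200, minus strand, mm10) stood at 13733 ± 15.1 TPM in MGS and 1599 ± 83.2 in CV, a log2 fold change of 3.10 (SE 0.11, adjusted p = 1.34e-06). Acta2 (chromosome 19, 34240336 to 34255373, minus strand) stood at 243 ± 14.3 TPM in MGS and 2622 ± 230 in CV, a log2 fold change of -3.42 (SE 0.10, adjusted p = 7.99e-07). Genes of complement, interferon response, acute reactivity and immediate early response were higher in MGS, and genes of the cell cycle, cholesterol synthesis and contractile actin were lower. Markers of microglia, oligodendrocytes, endothelium, ependyma and meningeal fibroblasts were also higher in MGS at this day. In the model fitted across all genes (limma, Benjamini-Hochberg adjustment), 7291 of 14904 genes differed, 3351 higher and 3940 lower in MGS, of which 3505 differed at least 2-fold. The median log2 fold change of all genes was -0.142, and changes of gene lists below are medians relative to it.

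The gene with the highest rise at day 5 was Cldn11, a tight junction claudin of oligodendrocytes and of the barrier cells of the meninges (chromosome 3, 31149920 to 31164326, plus strand), at 946 ± 18.8 TPM in MGS against 0.934 ± 0.643 in CV (log2 fold change 8.98, SE 0.22). It was followed by Lcn2, the iron-binding acute phase protein lipocalin-2 (chromosome 2, 32384637 to 32387739, minus strand), at 649 ± 8.24 TPM against 0.343 ± 0.484 (8.97, SE 0.25). Next came Ptgds, prostaglandin D synthase, at 7392 ± 1231 TPM in MGS (7.41, SE 0.17), and Dcn, the proteoglycan decorin (7.31, SE 0.26). Stra6, a retinol transporter (7.15), Ttr, the thyroxine carrier transthyretin (7.08), Slc6a13 (6.94), the imprinted RNA H19 (6.76), Col3a1 (6.72) and the myelin gene Mbp (6.58) completed the 10 with the highest rise, with SEs from 0.11 to 0.26. Ttr differed between its own replicates, at 12453 and 16841 TPM in the MGS libraries. Among the genes lower in MGS, the morphogen gene Shh led with -5.42 (SE 0.21, 0.312 ± 0.0118 against 55.0 ± 0.0790 TPM), followed by Crct1 (-5.06), the endocytic receptor gene Lrp2 (-4.79), Thbs1, thrombospondin-1 (-4.70), Sertm1 (-4.68), Klhdc8a (-4.67) and Pcp4 (-4.66). The stress cytokine gene Gdf15 (-4.51), the peptidase gene Mme (-4.36) and Coch (-4.30) came next.

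Of the 32 homeostatic astrocyte genes, 16 were higher and 8 lower in MGS at day 5, with a median 0.70 above that of all genes (camera, adjusted p = 0.00103, but adjusted p = 0.585 with an estimated correlation). The connexin gene Gjb6 (5.98), the neurotensin receptor gene Ntsr2 (3.85) and the lipid carrier gene Apoe (2.71) were among those that rose. The water channel gene Aqp4 did not differ (-0.01, SE 0.35, adjusted p = 0.979), nor did the glutamate transporter gene Slc1a3 (0.24, SE 0.27, adjusted p = 0.485). Without CV day 5 replicate 1 or 2 Aqp4 stood at -0.31 or 0.29 and Slc1a3 at 0.016 or 0.47, none of them called. The glutamate transporter gene Slc1a2 (0.69, SE 0.17) and S100b (1.25, SE 0.11) were higher, and Aldh1l1 (-0.69, SE 0.10) was lower. All except 2 of the 13 pan-reactive genes were higher in MGS (relative median 1.51, adjusted p = 2.74e-05, but adjusted p = 0.148 with an estimated correlation), led by Lcn2, Steap4 (5.25), Serpina3n, a serine protease inhibitor (4.90), and Gfap. The exceptions were Cd44 (-0.98) and Vim, vimentin (-0.92, SE 0.11), which were lower. The Slc1a2 call was lost without MGS day 5 replicate 1 (adjusted p = 0.0658) or 2 (0.0881) and without CV day 5 replicate 1 (0.0537). The Cd44 call was lost without MGS day 5 replicate 1 (0.0566) or CV day 5 replicate 2 (0.063), and the Vim call was lost after median-of-ratios scaling (0.0808). After a correction for transcript length and GC content Slc1a3 was called higher (0.45, adjusted p = 0.0136), and with a replicate block added Aqp4 was as well (0.36, adjusted p = 0.0413). Of the 12 A1 genes, 8 were higher and 0 lower (relative median 2.70, adjusted p = 2.74e-05, but adjusted p = 0.188 with an estimated correlation), led by the complement gene C3 (5.41), Serping1 (4.63) and Gbp2 (3.55). Adjusted over the list alone, 9 A1 genes rose and 1 fell. Of the A1 genes, C3 and Serping1 are also on the complement list, and H2-T23, H2-D1 and Psmb8 on the class I antigen presentation list. The results of these lists, here and below, therefore rest in part on the same genes. The 11 A2 genes split evenly, 4 higher and 4 lower, and the list was not called (adjusted p = 0.73).

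Most immune response genes were higher in MGS at day 5. Of 26 interferon-stimulated genes 23 were higher, with Oasl2 (4.19), Isg15 (3.65) and Ifi27l2a (3.57) in the lead, and Ifit2 was the 1 that fell (-1.24). Their relative median was 2.07 (adjusted p = 9.76e-11, but adjusted p = 0.188 with an estimated correlation), and adjusted over the list alone 24 rose. Of 14 class I antigen presentation genes 12 rose and 0 fell, led by H2-T23 (3.11) and the immunoproteasome gene Psmb8 (2.50), with adjusted p = 3.85e-06, but adjusted p = 0.0674 with an estimated correlation. Of 13 complement genes 11 rose, C3 among them (relative median 3.20, adjusted p = 3.5e-07, but adjusted p = 0.282 with an estimated correlation). Of 22 cytokine and NF-kB genes 16 rose and 4 fell, led by the chemokine genes Cxcl1 (4.23) and Cxcl12 (3.38), with adjusted p = 4.58e-05, but adjusted p = 0.367 with an estimated correlation. Of 18 immediate early genes 15 rose, among them Fosb (5.05) and Fos (3.81), and 2 fell, Fosl1 (-3.21) and Klf6 (-0.97). The relative median of that list was 2.40 (adjusted p = 2.92e-07, but adjusted p = 0.282 with an estimated correlation). The calls of Ifit2 and Klf6 were lost without MGS day 5 replicate 1 (adjusted p = 0.103 and 0.0728) or 2 (0.0886 and 0.0775) and without CV day 5 replicate 2 (0.136 and 0.102). In the same libraries 16 of 18 microglia markers were higher in MGS, with a relative median of 2.80 (adjusted p = 8.01e-11, but adjusted p = 0.0542 with an estimated correlation).

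Growth and lipid synthesis genes were lower in MGS at day 5. Of 34 cell cycle genes 33 fell and 0 rose, with Rrm2 (-2.39), Cenpf (-2.10) and Cenpe (-1.91) changed most, and adjusted over the list alone all 34 fell. The proliferation marker gene Mki67 stood at 24.3 ± 0.129 TPM in MGS and 78.5 ± 22.3 in CV (-1.62, SE 0.24). The relative median of the list was -1.26 (adjusted p = 8.01e-11, but adjusted p = 0.284 with an estimated correlation). All 25 cholesterol synthesis genes fell, led by Idi1 (-3.08) and Insig1 (-3.005), with a relative median of -2.10 (adjusted p = 2.07e-11, but adjusted p = 0.188 with an estimated correlation). Of 18 p53 targets 15 fell, among them Gdf15 and the apoptosis gene Pmaip1 (-3.71), and Btg2 rose (2.29), with adjusted p = 6.3e-05 for the list, but adjusted p = 0.284 with an estimated correlation.

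The actin and SRF/MRTF list, which holds cytoskeletal genes, had 17 of 28 members lower and 3 higher in MGS at day 5. The calponin gene Cnn1 (-3.77), Acta2, the transgelin gene Tagln (-2.80) and Lmod1 (-2.28) changed most, while Actg2 (2.13), Fhl2 (0.86) and Tpm2 (0.49) rose. The relative median was -0.58 (adjusted p = 4.58e-05, but adjusted p = 0.282 with an estimated correlation), and adjusted over the list alone 21 fell. The call of Tpm2 was lost without any single library other than those of CV at day 32 (adjusted p from 0.0594 to 0.175), after median-of-ratios scaling (0.0571) and after the length and GC correction (0.3). Of 22 YAP/TAZ targets 11 fell and 4 rose. The connective tissue growth factor gene Ctgf (-1.997, SE 0.11) and Cyr61 (-0.82, SE 0.12) were lower. Ankrd1, fixed beforehand, stood at 2.26 ± 0.229 TPM in CV and 0.0178 ± 0.0251 in MGS (-1.68, SE 0.14). The YAP/TAZ list was called (adjusted p = 0.0464, but adjusted p = 0.763 with an estimated correlation), and it was not called after a length and GC correction (adjusted p = 0.161), with quantile normalization (0.117) or without CV day 5 replicate 1 (0.0546). Of 23 focal adhesion genes 16 fell, with the integrin gene Itga3 (-3.04) in the lead, and 3 rose (adjusted p = 0.0399, but adjusted p = 0.763 with an estimated correlation). That call of the focal adhesion and integrins list was lost without CV day 5 replicate 2 (adjusted p = 0.0533) and with quantile normalization (0.106). The 10 mechanosensitive channel genes split, 3 higher, led by Piezo2 (2.51), and 3 lower (adjusted p = 0.875).

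Of 27 collagen and fibrous matrix genes 15 were higher and 7 lower at day 5, with Col3a1, Col6a3 (4.43) and Col1a2 (4.11) among the higher and Thbs1 among the lower (relative median 1.06, adjusted p = 0.00568, but adjusted p = 0.735 with an estimated correlation). In the same libraries 12 of 13 meningeal fibroblast markers rose, led by Ptgds, Dcn, Slc6a13 and Igf2 (6.07), and Igfbp2 was the exception (-2.73). Their relative median was 5.19 (adjusted p = 6.07e-10, but adjusted p = 0.0542 with an estimated correlation). All 9 ependymal markers rose, led by Ccdc153 (4.96), with a relative median of 3.11 and adjusted p = 2.12e-07, but adjusted p = 0.0542 with an estimated correlation. All 10 oligodendrocyte markers rose, with Cldn11, Mbp and Mag (4.70) first (relative median 2.47, adjusted p = 3.21e-08, but adjusted p = 0.112 with an estimated correlation). Of 10 oligodendrocyte precursor markers 7 rose, led by Pdgfra (5.47), and Olig2 (-1.96) and Olig1 (-1.72) fell (adjusted p = 0.00639, but adjusted p = 0.255 with an estimated correlation). Of 11 endothelial markers 8 rose, led by Cdh5 (4.98) and Cldn5 (4.55), and Kdr fell (-1.14), with adjusted p = 7.71e-05, but adjusted p = 0.112 with an estimated correlation. Of 7 mural markers 5 rose, led by Vtn (6.05), and Mcam fell (-2.07), with adjusted p = 0.0139, but adjusted p = 0.201 with an estimated correlation.

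The neural stem list was lower at day 5, with 11 of 20 members down, Nes, nestin, among them (-2.05), and Hes5 up (1.65), with adjusted p = 0.0236, but adjusted p = 0.585 with an estimated correlation. Other lists were not called at day 5. They were the proteoglycans (5 higher, 7 lower, adjusted p = 0.576), matrix proteases (8 and 5, 0.222), TGF-beta and BMP response (4 and 12, 0.125), synapse-acting secreted factors (4 and 9, 0.263) and hypoxia and glycolysis (9 and 11, 0.968). The others were nuclear oxidative phosphorylation (0 and 9, 0.0657), stress and unfolded protein response (3 and 7, 0.263) and neuron markers (6 and 4, 0.664). With quantile normalization the neuron markers had 4 higher and 6 lower, and after median-of-ratios scaling the proteoglycans had 7 higher and 6 lower. The lower count of nuclear oxidative phosphorylation was 5 after median-of-ratios scaling, 6 with FPKM and 19 after the length and GC correction, and that of the stress list 12 after this correction. Nuclear oxidative phosphorylation was called lower after the length and GC correction (adjusted p = 0.00463), without a filter (0.0293) and without CV day 5 replicate 2 (0.0154). The files listed 0 genes of the mitochondrial chromosome, so the list of mitochondrially encoded genes could not be measured. Adjusted over the list alone, the counts above became 12 lower for YAP/TAZ targets, 4 higher for focal adhesion, 5 lower for channels and 16 higher for collagen and fibrous matrix. They became 12 lower for neural stem genes, 6 lower for oxidative phosphorylation, 5 lower for neuron markers and 2 lower for mural markers, and the others not given were the same. Without MGS day 5 replicate 1 the count of genes that differed at day 5 was 4555, and without replicate 2 it was 4523. The share of calls that were higher in MGS, 46%, stayed between 40.2% and 54.4% under other scalings of the values.

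**Figure D1:**
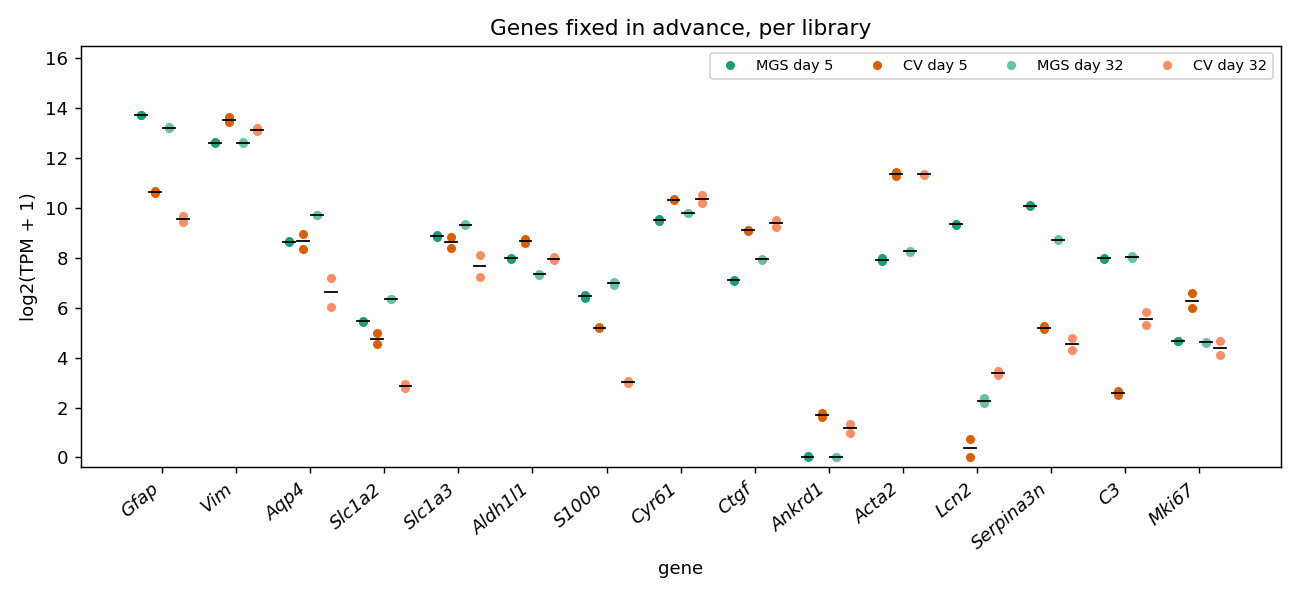
Levels of the 15 genes fixed beforehand, as log2(TPM + 1) per library on the vertical axis, with 1 point per library, a black bar for the mean of the 2 libraries of a group, and a colour for each group. Gfap lies higher in both MGS groups than in both CV groups, Acta2 lies lower, and Lcn2 is high in MGS at day 5 only, at 649 TPM against 3.83 at day 32.

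By day 32 several astrocyte genes differed more widely between MGS and CV than at day 5, and microglia markers differed the other way. Aqp4 stood at 842 ± 1.51 TPM in MGS and 105 ± 56.3 in CV (log2 fold change 3.11, SE 0.35, adjusted p = 0.000207), and Slc1a2 at 80.7 ± 0.291 against 6.24 ± 0.497 (3.50, SE 0.17). Gfap was again higher in MGS, at 9588 ± 23.9 against 754 ± 81.9 TPM (3.67, SE 0.11), and Acta2 again lower, at 305 ± 4.94 against 2609 ± 27.3 (-3.09, SE 0.10). Among the microglia markers, Lyz2, the lysozyme of macrophages and microglia (chromosome 10, 117277541 to 117282272, minus strand), stood at 687 ± 14.3 TPM in MGS and 10316 ± 1222 in CV (-3.90). In the same model 10075 of 14904 genes differed, 7862 higher and 2213 lower in MGS, of which 5710 differed at least 2-fold.

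The split of these calls rests on the scaling. With TPM as deposited 78% of the calls at day 32 were higher in MGS, but the share was 50.2% after median-of-ratios scaling, 47.1% after quantile normalization, 61.3% with FPKM and 43.8% after a correction for transcript length and GC content. The median log2 fold change of all genes was 0.558 with TPM as deposited and -0.002 after median-of-ratios scaling. It also rose with transcript length, from -0.15 in the shortest eighth of genes to 1.37 in the longest, while at day 5 it went from 0.11 to -0.49. Between the 2 CV libraries of day 32 the longest eighth exceeded the shortest by 0.78, against 0.38 between those of CV at day 5 and 0.06 and 0.04 within the MGS groups. Changes of gene lists are therefore given relative to the median of all genes, but the counts of members higher or lower carry the shift. Single genes carry the shift, and after the correction for length and GC content Slc1a2 stood at 1.85, Slc1a3 at 0.86, Acan at 2.26, Ncan at 2.25 and Vcan at 1.96, against 3.50, 1.68, 3.62, 3.60 and 3.59 with TPM as deposited.

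**Figure D2:**
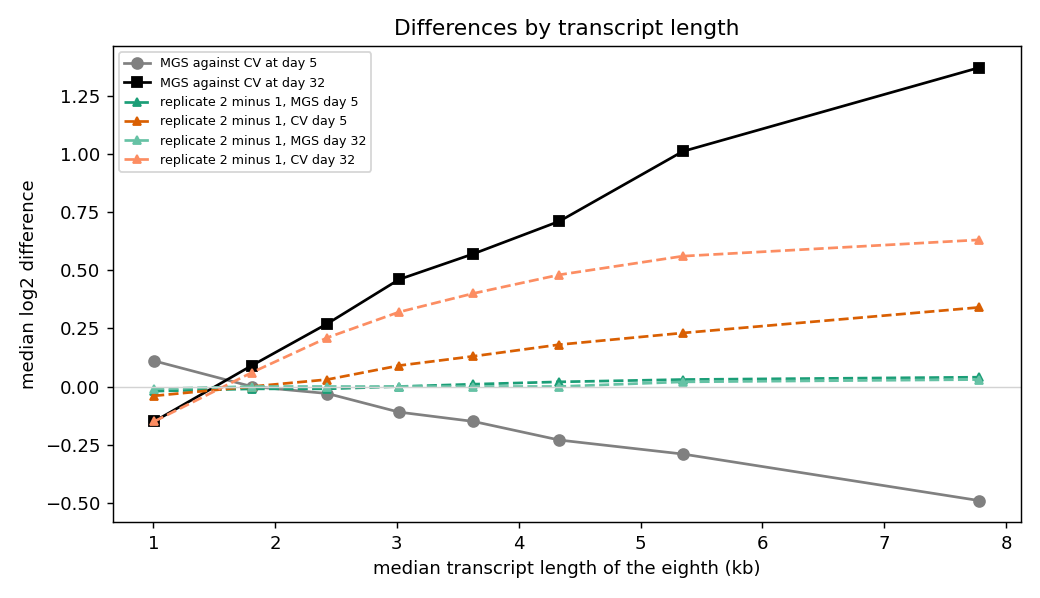
Median log2 difference (vertical axis) in 8 groups of genes by transcript length, at the median length of the group in kilobases (horizontal axis). Solid lines show MGS against CV at each day and dashed lines replicate 2 minus replicate 1 within each group. At day 32 the difference climbs from -0.15 in the shortest eighth to 1.37 in the longest, the replicates of CV at day 32 differ by -0.15 to 0.63, and those of MGS at day 32 by -0.01 to 0.03.

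The largest rises at day 32 were those of Cldn11 (7.62, SE 0.22), Ptgds (7.41, SE 0.17), Myoc, the secreted glycoprotein myocilin (7.32, SE 0.14, 289 ± 2.83 against 0.810 ± 0.00398 TPM), and the connexin gene Gjb2 (6.94, SE 0.14). Gjb6 (6.49, SE 0.21), the E-cadherin gene Cdh1 (6.37, SE 0.16), Thsd4 (6.20, SE 0.15) and Enpp2 (6.19, SE 0.20) also ranked among the 10 highest. The ribosomal protein gene Rps27 passed the test as well (6.62, SE 1.83), but its replicates in CV at day 5 read 7.99 and 1144 TPM and it has near-identical pseudogene copies, so its value is uncertain. The call was lost without MGS day 32 replicate 1 (adjusted p = 0.0651) or 2 (0.0604). Lower in MGS at day 32 were Cd72, a receptor of B cells and myeloid cells (-6.60, SE 0.14, 5.27 ± 0.346 against 608 ± 9.36 TPM), Slco4a1 (-5.68, SE 0.17), Cd34 (-5.16, SE 0.21), Crct1 (-5.12, SE 0.19), Fxyd2 (-4.97, SE 0.27) and Ly86, which pairs with a Toll-like receptor relative (-4.58, SE 0.18). The prolactin family genes Prl2c2 and Prl2c3 were listed at 0 in the MGS libraries of both days and reached 229 ± 24.7 and 128 ± 9.70 TPM in CV at day 32. They are near-identical copies, so the division of reads between them is uncertain. Iapp and Sprr2b were also listed at 0 in MGS and reached 62.0 ± 0.516 and 39.3 ± 2.71 TPM in CV at day 32.

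Of 32 homeostatic astrocyte genes 26 were higher and 2 lower in MGS at day 32, with a relative median of 1.43 (adjusted p = 0.000292, but adjusted p = 0.744 with an estimated correlation). Gjb6, Ntsr2 (6.05) and the connexin gene Gja1 (4.23) were among those higher, S100b (3.98, SE 0.11) and Slc1a3 (1.68, SE 0.27) were higher, and Cbs (-0.62) and Aldh1l1 (-0.61, SE 0.10) were the 2 lower ones. The 13 pan-reactive genes split into 8 higher, Serpina3n first (4.19, SE 0.15), and 4 lower, Timp1 first (-2.61), and the list was not called (adjusted p = 0.948), with 5 higher and 6 lower after the length and GC correction. Lcn2, so high in MGS at day 5, was lower than in CV at day 32 (3.83 ± 0.449 against 9.43 ± 0.928 TPM, -1.11, SE 0.25), and Vim was lower too (-0.51, SE 0.11). The Lcn2 call at day 32 was lost at a pseudocount of 0.1 (adjusted p = 0.196). The Vim call was lost without MGS day 32 replicate 1 (adjusted p = 0.0608) or 2 (0.0534), and its direction turned with quantile normalization (0.25). Of the 12 A1 genes 5 rose, C3 first (2.47, SE 0.17), and 5 fell, Fbln5 first (-2.14), with no call for the list (adjusted p = 0.168). The 11 A2 genes, with 5 higher and 4 lower, gave no call either (adjusted p = 0.284). Of the 10 oligodendrocyte precursor markers 9 were higher, led by Pdgfra (5.56) and Lhfpl3 (5.21), and Olig1 was lower (-0.54), with a relative median of 2.85 (adjusted p = 0.00977, but adjusted p = 0.424 with an estimated correlation). That call was lost without CV day 32 replicate 2 (adjusted p = 0.0721).

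Microglia markers gave the strongest list result at day 32. Of the 18, 17 were lower in MGS and 0 higher, led by Ly86, Aif1 (-4.06), Lyz2 and Trem2 (-3.68), and Ptprc did not pass (-1.19), although it did without CV day 32 replicate 1 (-2.58), and without replicate 2 it turned to 0.19. Ptprc was also called lower with quantile normalization (-2.16, adjusted p = 0.0132) and after the length and GC correction (-2.17, 0.0118). Their relative median was -3.78 (adjusted p = 1.72e-18, and adjusted p = 0.021 with an estimated correlation). In the same libraries class I antigen presentation genes were lower in MGS, 8 of 14, with Psmb8 (-1.61) and the beta-2 microglobulin gene B2m (-1.23) ahead, and Erap1 was higher (1.21). The Erap1 call was lost without MGS day 32 replicate 1 (adjusted p = 0.0728) or 2 (0.0585) and after the length and GC correction (0.16). Without CV day 32 replicate 1 the fold change of Erap1 was 0.65. The relative median of the class I list was -0.92 (adjusted p = 0.000456, but adjusted p = 0.192 with an estimated correlation). The 26 interferon-stimulated genes split into 11 higher and 7 lower, Ifi27l2a lowest (-2.88), with no call (adjusted p = 0.142), and adjusted over the list alone 8 were lower. The interferon-stimulated counts were 3 higher and 10 lower after median-of-ratios scaling and with quantile normalization, 7 and 9 with FPKM, and 7 and 12 after the length and GC correction. The 22 cytokine and NF-kB genes split into 9 higher, Cxcl12 first (3.59), and 3 lower, Il1b first (-3.02), with no call either (adjusted p = 0.715). Under the same scalings the cytokine and NF-kB counts were 6 and 10, 8 and 10, 7 and 6, and 8 and 8, and the lower count of the class I list was 10 to 13. Of 13 complement genes 11 were higher, C4b first (3.84), and Cd59a was lower (-0.93), with a relative median of 1.303 (adjusted p = 0.0464, but adjusted p = 0.838 with an estimated correlation). The complement call was lost with quantile normalization (adjusted p = 0.0747), without CV day 5 replicate 1 or 2, without CV day 32 replicate 2, and with a replicate block. Of 18 immediate early genes 15 were higher, Nr4a1 (4.51) and Egr3 (4.20) first, and Fosl1 was lower (-1.33), with adjusted p = 0.0464, but adjusted p = 0.838 with an estimated correlation. This immediate early call was lost as well without CV day 5 replicate 1 or 2, without CV day 32 replicate 2, and with a replicate block.

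**Figure D3:**
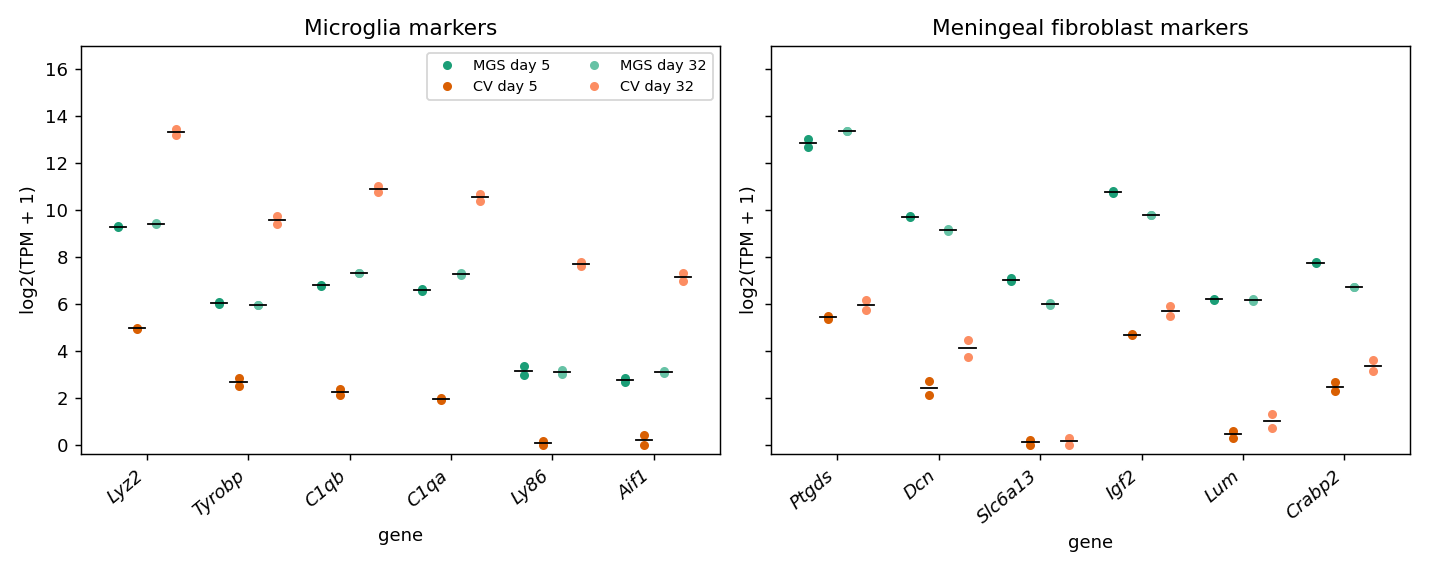
Levels of 6 microglia markers (left) and 6 meningeal fibroblast markers (right), as log2(TPM + 1) per library on the vertical axis, with 1 point per library, a black bar for the mean of the 2 libraries of a group, and a colour for each group. Lyz2 reaches 10316 TPM in CV at day 32 against 30.2 in CV at day 5, while Ptgds stands at 42.2 and 61.4 TPM in CV and at 7392 and 10514 in MGS, and Dcn at 4.42 and 16.9 in CV, at day 5 and day 32.

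Contractile genes were lower in MGS at day 32 as well. Of 28 actin and SRF/MRTF genes 20 were lower, led by Cnn1 (-3.94), Acta2, Actg2 (-2.56) and Tpm2 (-2.49), and Flnc was higher (0.69), but lower after the length and GC correction (-0.90). The Flnc call was lost after median-of-ratios scaling (0.068, adjusted p = 0.551), with quantile normalization (0.23, 0.0671), with only the libraries compared (0.05) and without MGS day 32 replicate 2 (0.065), and without CV day 32 replicate 1 its fold change was 0.43. The relative median of the actin and SRF/MRTF targets was -1.48 (adjusted p = 9.94e-14, but adjusted p = 0.192 with an estimated correlation), or -0.78 with quantile normalization. Ctgf (-1.45, SE 0.11), Cyr61 (-0.55, SE 0.12) and Ankrd1 (-1.17, SE 0.14) were lower, but the 22 YAP/TAZ targets, 9 higher and 7 lower, gave no call (adjusted p = 0.166), with 6 higher and 9 lower after median-of-ratios scaling and 4 and 13 after the length and GC correction, and the Cyr61 call was lost with quantile normalization (adjusted p = 0.467). Of 34 cell cycle genes 17 were lower, with Tk1 (-1.51) and Birc5 (-1.32) first, and Kif11 was higher (0.89). The Kif11 call was lost after each of the other scalings, with only the libraries compared (adjusted p = 0.0568), and without MGS day 32 replicate 1 (adjusted p = 0.0896) or 2 (0.0791) or CV day 32 replicate 1 (0.0612). The cell cycle list had a relative median of -1.01 (adjusted p = 1.22e-08, but adjusted p = 0.558 with an estimated correlation). Mki67 did not differ with TPM as deposited (0.21, SE 0.24, adjusted p = 0.453), or without CV day 32 replicate 1 (-0.076, adjusted p = 0.773) or 2 (0.50, 0.0697), but was lower in MGS after median-of-ratios scaling (-0.39, adjusted p = 0.049), quantile normalization (-0.50, 0.0232) and the length and GC correction (-1.39, 9.44e-06). Of 18 p53 targets 8 were lower, Gdf15 first (-2.39), and Btg2 was higher (1.10), with adjusted p = 3.49e-05, but adjusted p = 0.469 with an estimated correlation. The 25 cholesterol synthesis genes, all lower at day 5, were split at day 32, with 7 higher and 4 lower (adjusted p = 0.16). Under each other scaling more of them were lower than higher, with 5 higher and 15 lower after median-of-ratios scaling, 6 and 12 with quantile normalization, 6 and 10 with FPKM, and 3 and 16 after the length and GC correction. Lower counts of the cell cycle list became 25 to 32 under these scalings, and those of the p53 targets 13 to 15.

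Proteoglycan and perineuronal matrix genes were higher in MGS at day 32, 15 of 19, led by Tnr, tenascin-R (6.01), the aggrecan gene Acan (3.62), Ncan (3.60) and Vcan (3.59), with 3 lower. Their relative median was 1.77 (adjusted p = 0.0396, but adjusted p = 0.838 with an estimated correlation), and the call was lost without CV day 32 replicate 2 (adjusted p = 0.103). In the same libraries 9 of 10 oligodendrocyte precursor markers were higher, with a relative median of 2.85, and Cspg4 is on both lists. Meningeal fibroblast markers were again higher, 12 of 13, with Ptgds, Slc6a13 (5.86), Lum (5.15) and Dcn (5.03) first and Igfbp2 lower (-2.85), with a relative median of 2.76 (adjusted p = 0.000456, but adjusted p = 0.192 with an estimated correlation). Beside them, of 27 collagen and fibrous matrix genes 18 were higher, Col6a3 first (4.69), and 3 lower, but the list was not called (adjusted p = 0.372). The collagen counts were 16 higher and 9 lower after median-of-ratios scaling, 18 and 6 with quantile normalization, and 18 and 7 with FPKM. After the length and GC correction they were 10 and 13, with a relative median of 0.15 against 0.65. All 9 ependymal markers were higher, Tmem212 (5.98) and Ccdc153 (5.24) first (adjusted p = 0.000188, but adjusted p = 0.192 with an estimated correlation). Of 10 oligodendrocyte markers 9 were higher, Cldn11 first (adjusted p = 0.00109, but adjusted p = 0.424 with an estimated correlation).

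Of 30 nuclear oxidative phosphorylation genes 8 were lower and 3 higher at day 32, with a relative median of -0.74 (adjusted p = 0.000188, but adjusted p = 0.558 with an estimated correlation), or -0.43 without CV day 32 replicate 1. This direction rests on the scaling, since the relative median was 0.02 with quantile normalization and the call was lost there and after the length and GC correction (adjusted p = 0.0776). The stress and unfolded protein response list had 5 higher, Slc7a11 first (3.35), and 5 lower (adjusted p = 0.0464, but adjusted p = 0.558 with an estimated correlation). The call of this integrated stress and unfolded protein response list was lost with median-of-ratios scaling (adjusted p = 0.0522), with quantile normalization (0.378) and after the length and GC correction (0.244). It was also lost without MGS day 32 replicate 2 or CV day 32 replicate 2, and with a replicate block. Not called at day 32 were focal adhesion (12 higher, 5 lower, adjusted p = 0.644), mechanosensitive channels (6 and 2, 0.993), matrix proteases (12 and 5, 0.843), neural stem genes (13 and 4, 0.528) and TGF-beta and BMP response (9 and 5, 0.528). Nor were synapse-acting secreted factors (10 and 2, 0.824), hypoxia and glycolysis (16 and 2, 0.258), neuron markers (8 and 2, 0.993), endothelial markers (6 and 0, 0.633) and mural markers (6 and 1, 0.179). These counts rest on the scaling. Focal adhesion had 7 higher and 9 lower after median-of-ratios scaling and 4 and 13 after the length and GC correction, TGF-beta and BMP response 4 and 6, and 6 and 10, and hypoxia and glycolysis 11 and 9, and 13 and 9. With quantile normalization neuron markers had 4 higher and 5 lower and endothelial markers 2 and 3. The stress and unfolded protein response list had 3 or 4 higher and 11 to 13 lower under the other scalings, and nuclear oxidative phosphorylation had 25 lower after median-of-ratios scaling. Adjusted over the list alone, the counts at day 32 became 3 lower for channels, 17 higher for hypoxia and glycolysis, 7 lower for oxidative phosphorylation and 2 lower for immediate early genes, and the others not given were the same.

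The calls of both days overlapped. Of the 5104 genes that differed at both days, 3265 went the same way. Of these, 2330 were higher in MGS, where 1767.7 would be shared by independent lists (Fisher's exact test, one-sided, p = 5.16e-111). The remaining 935 were lower in MGS, where 585 would be shared (Fisher's exact test, one-sided, p = 2.7e-69). The other 1839 of the 5104 genes went opposite ways. Genes are not independent replicates, and both lists of calls used the same estimate of the spread. The p-values of the overlap therefore do not measure replication. Across genes the log2 fold changes of both days correlated with r = 0.315. The direction of the shared calls rests on the scaling. Higher and lower shared calls numbered 2272 and 1588 after median-of-ratios scaling and 2426 and 1350 with FPKM. They numbered 1874 and 2195 with quantile normalization, and 2173 and 3210, 5383 in all, after the length and GC correction.

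Within MGS, from day 5 to day 32, Lcn2, Saa3 and Reg3g, genes of acute phase proteins, fell, and ependymal markers and genes of cholesterol synthesis and interferon response rose. Lcn2 dropped from 649 to 3.83 TPM (log2 fold change -7.07, SE 0.25), Saa3, a serum amyloid, fell by 4.0 on the log2 scale (SE 0.24), Reg3g fell by 3.48 (SE 0.13) and the macrophage gene Cd5l fell by 3.48 (SE 0.13). The endothelial claudin gene Cldn5 went from 23.6 ± 0.295 to 0.0831 ± 0.0398 TPM (-4.50, SE 0.11). Myoc rose from 8.96 ± 0.00121 to 289 ± 2.83 TPM (4.86, SE 0.14), followed by the phosphatase gene Inpp5j (4.70, SE 0.14), Tnr (4.42, SE 0.20) and C1ql3 (4.16, SE 0.26). The uncertain Rps27 also rose (6.03, SE 1.83), a call lost without any single MGS library (adjusted p from 0.127 to 0.136) and without a filter (0.0529). In the model 6335 genes differed, 5212 higher and 1123 lower at day 32.

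Of the 13 pan-reactive genes 8 fell from day 5 to day 32 in MGS and 0 rose (relative median -0.82, or -0.47 with quantile normalization, adjusted p = 2.85e-06, but adjusted p = 0.138 with an estimated correlation), Steap4 (-2.67) and Timp1 (-2.11) after Lcn2. All 9 ependymal markers rose, Dnahc11 first (2.82), with a relative median of 1.18 (adjusted p = 1.51e-05, but adjusted p = 0.108 with an estimated correlation). Of 25 cholesterol synthesis genes 19 rose, Insig1 first (1.69), and 0 fell (adjusted p = 0.00165, but adjusted p = 0.62 with an estimated correlation). Of 26 interferon-stimulated genes 17 rose, Ifit3 first (2.29), and 0 fell (adjusted p = 0.00266, but adjusted p = 0.62 with an estimated correlation). Of 34 cell cycle genes 22 fell, Birc5 first (-1.52), and 0 rose, with a relative median of -1.07 (adjusted p = 5.74e-18, but adjusted p = 0.321 with an estimated correlation). Of 27 collagen and fibrous matrix genes 10 fell and 4 rose, Thbs1 the most (2.84), with a relative median of -0.83, or -0.36 with quantile normalization (adjusted p = 5.91e-05, but adjusted p = 0.639 with an estimated correlation). Markers of other cell types fell beside them, 7 of 13 for meningeal fibroblasts, with Ptgds higher (0.52), 6 of 11 for endothelium, with Kdr higher (1.15), and 4 of 7 for mural cells. The lists had adjusted p = 1.04e-06, 6.18e-08 and 0.000311 in that order. With an estimated correlation none of these 3 was called (adjusted p = 0.108, 0.108 and 0.138). Of 10 oligodendrocyte markers 4 fell, Mag (-1.88), Mbp (-1.82), Opalin (-1.08) and Cldn11 (-0.68), and Cnp rose (0.72), with adjusted p = 0.000302, but adjusted p = 0.309 with an estimated correlation. Of 13 neuron markers 5 fell, Nefl first (-1.70), and Map2 (1.53) and Syn1 (0.52) rose, with adjusted p = 0.000181, but adjusted p = 0.321 with an estimated correlation. The call of the neuron markers was lost among genes with a mean TPM of at least 5 (adjusted p = 0.397), that of Cnp after median-of-ratios scaling (0.106) and that of Map2 without MGS day 5 replicate 1 (0.0554). The Syn1 call was lost without any single library other than those of CV at day 32 (0.0515 to 0.169), at a pseudocount of 0.1 (0.0542) and with a replicate block within day (0.0727). It was also lost after median-of-ratios scaling (0.235) and with FPKM (0.0612), and Syn1 turned to -0.10 with quantile normalization. The Kdr call was lost without any single MGS library (adjusted p from 0.0534 to 0.0639). The Ptgds call was lost without any single library other than those of CV at day 32 (0.0629 to 0.261), after median-of-ratios scaling (0.817) and with FPKM (0.372), and narrowly at a pseudocount of 0.1 (0.0526), without a filter (0.0615) and without a variance trend (0.0603). Of 18 microglia markers 9 rose, Csf1r first (2.53), and Tmem119 fell (-1.39), with no call for the list (adjusted p = 0.416). Microglia markers that rose and fell numbered 5 and 3 after median-of-ratios scaling and 8 and 4 with quantile normalization. They numbered 6 and 2 with FPKM, and 9 and 2 after the length and GC correction. Adjusted over the list alone, the counts became 11 lower for collagen and fibrous matrix, 20 higher for cholesterol synthesis, 2 higher and 7 lower for endothelium, 5 lower for oligodendrocytes and 2 lower for microglia markers, and the others given here were the same. Under other scalings the number that fell reached 20 for collagen and fibrous matrix, 34 for the cell cycle, 11 for fibroblast, 9 for endothelial, 6 for mural, 7 for oligodendrocyte and 10 for neuron markers. The share of calls that were higher at day 32 was 82.3% with TPM as deposited, 50.3% after median-of-ratios scaling, 48.1% after quantile normalization, 65% with FPKM and 46% after the length and GC correction. The count rested on single libraries and was 2455 or 2746 without MGS day 5 replicate 1 or 2, 2677 or 2504 without MGS day 32 replicate 1 or 2, and 9723 or 9732 without CV day 32 replicate 1 or 2.

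Within CV, from day 5 to day 32, microglia genes rose from low to high levels while homeostatic astrocyte, cell cycle and cholesterol synthesis genes fell. Lyz2 rose from 30.2 ± 0.846 to 10316 ± 1222 TPM (8.36, SE 0.11), the complement component genes C1qb (8.64, SE 0.13) and C1qa (8.59, SE 0.13) with it, and Cd72 (9.18, SE 0.14) and Fcrls (8.32, SE 0.16) likewise. All 18 microglia markers rose, with a relative median of 7.15 (adjusted p = 2.56e-23, and adjusted p = 0.0133 with an estimated correlation). Falling most were Pcp4 (-4.78, SE 0.14), the GABA transporter gene Slc6a11 (-4.23, SE 0.14), the neurocan gene Ncan (-4.17, SE 0.16), the glycolytic regulator gene Pfkfb3 (-4.06, SE 0.66) and Matn3 (-4.05, SE 0.13). In the model 7997 genes differed, 2381 higher and 5616 lower at day 32. That count rests in part on the spread shared with the less variable MGS libraries. It was 3483 with only the libraries compared and 4895 with a variance weight per group.

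Beside the microglia markers, 25 of 26 interferon-stimulated genes rose in CV, Ifi27l2a (6.84) and Oas1a (4.92) first, with a relative median of 2.99 (adjusted p = 6.87e-20, but adjusted p = 0.143 with an estimated correlation). Of 14 class I antigen presentation genes 11 rose and 0 fell (adjusted p = 1.71e-09, but adjusted p = 0.0511 with an estimated correlation). Of 13 complement genes 11 rose and 0 fell (adjusted p = 2.11e-07, but adjusted p = 0.477 with an estimated correlation). Of 12 A1 genes 9 rose and 0 fell, and Srgn rose most (4.95). That list had adjusted p = 6.08e-08, but adjusted p = 0.143 with an estimated correlation. Of 22 cytokine and NF-kB genes 12 rose, the cytokine genes Il1b (5.50) and Tnf (5.08) among them, and 3 fell (adjusted p = 1.34e-05, but adjusted p = 0.511 with an estimated correlation). Of 13 pan-reactive astrocyte genes 8 rose, Lcn2 first (3.004), and 5 fell, Aspg first (-2.53), with a relative median of 1.22 (adjusted p = 0.0299, but adjusted p = 0.511 with an estimated correlation). That call was lost after median-of-ratios scaling (adjusted p = 0.091), quantile normalization (0.137) and the length and GC correction (0.0717), and with FPKM (0.0638). Markers of other cell types went both ways. Of 13 meningeal fibroblast markers 7 rose, Dcn first (1.70), of 9 ependymal markers 5 rose, Pifo first (2.32), and 0 fell in both. These lists had adjusted p = 0.000136, but adjusted p = 0.143 with an estimated correlation. Of 13 neuron markers 9 fell, Snap25 first (-2.13), and Stmn2 rose (0.40), without a call for the list (adjusted p = 0.0599). The neuron markers were called lower after median-of-ratios scaling (adjusted p = 0.0168), with quantile normalization (0.0284), with FPKM (0.0389), at a pseudocount of 0.1 (0.0364), without a filter (0.0194) and without any single MGS library (0.0376 to 0.0482). The Stmn2 call was lost without any single library (0.0575 to 0.205), at a pseudocount of 0.1 (0.0503), without a filter (0.0518) or a variance trend (0.0531), with a replicate block (0.051) or one within day (0.0592), with group weights (0.372) and with only the libraries compared (0.113). Oligodendrocyte, endothelial and mural markers were not called (adjusted p = 0.271, 0.905 and 0.89). Of 32 homeostatic astrocyte genes 22 fell, Slc6a11 first, and Apoe (1.83) and Cbs (1.71) rose, with a relative median of -0.74 (adjusted p = 0.000577, but adjusted p = 0.627 with an estimated correlation), or -0.47 without CV day 32 replicate 1. All 34 cell cycle genes fell, Rrm2 first (-2.64), with adjusted p = 8.03e-10, but adjusted p = 0.511 with an estimated correlation. Of 25 cholesterol synthesis genes 23 fell, Stard4 first (-2.77), and 0 rose (adjusted p = 1.37e-06, but adjusted p = 0.477 with an estimated correlation). Of 19 proteoglycan genes 16 fell, Ncan and Xylt1 (-3.79) first, and Sdc4 rose (0.95), with adjusted p = 0.000748, but adjusted p = 0.619 with an estimated correlation. Beside them, of 10 oligodendrocyte precursor markers 6 fell, Cspg4 first (-2.07), and 0 rose, without a call for the list (adjusted p = 0.147). Of 20 neural stem genes 14 fell and 0 rose (adjusted p = 0.0015, but adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 1 interferon-stimulated gene, 4 cytokine and NF-kB genes and 1 complement gene fell, and the other counts given here were the same. The share of calls that were higher at day 32 was 29.8% with TPM as deposited, 50.4% after median-of-ratios scaling, 42.1% after quantile normalization, 43.8% with FPKM and 40.9% after the length and GC correction. Without CV day 5 replicate 2 the count was 4830.

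The change from day 5 to day 32 differed between the cultures for 9243 genes in the test of the interaction, 7407 with a higher and 1836 with a lower change in MGS than in CV. The share with a higher change was 80.1% with TPM as deposited, 47.6% after median-of-ratios scaling, 52.4% after quantile normalization, 60.8% with FPKM and 55.5% after the length and GC correction. Microglia markers carried the strongest list result, with 17 of 18 lower in MGS by this measure, Lyz2 (-8.23) and C1qb (-8.13) first, and a relative median of -7.07 (adjusted p = 8.94e-25, and adjusted p = 0.0118 with an estimated correlation). Class I antigen presentation was the other list called with an estimated correlation, with 11 of 14 lower and Erap1 higher (1.35, but -0.054 after the length and GC correction), a relative median of -2.59, or -1.70 after that correction (adjusted p = 4.5e-10, and adjusted p = 0.0444 with an estimated correlation). The Erap1 call was lost without any single library other than those of CV at day 32 (adjusted p from 0.0506 to 0.126), without a filter (0.0557), after median-of-ratios scaling (0.169), with quantile normalization (0.117) and with FPKM (0.0849). Without CV day 32 replicate 1 its value was 0.80. Interferon-stimulated genes were lower, 18 of 26, with Ifit2 higher (2.40). The list had adjusted p = 9.45e-15, but adjusted p = 0.167 with an estimated correlation. Of 12 A1 genes 9 were lower and 0 higher (adjusted p = 5.91e-09, but adjusted p = 0.137 with an estimated correlation). Of 13 complement genes 10 were lower and Hc (0.85) and Cd55 (1.23) higher (adjusted p = 1.35e-07, but adjusted p = 0.384 with an estimated correlation). The Hc call was lost without any single library other than CV day 5 replicate 1 and those of CV at day 32 (adjusted p from 0.071 to 0.0859), after median-of-ratios scaling (0.402), with quantile normalization (0.258) and with FPKM (0.106). After the length and GC correction Hc was lower (-0.51). The Cd55 call was lost without MGS day 5 replicate 1 (0.0512) or MGS day 32 replicate 1 (0.0574), after median-of-ratios scaling (0.0622) and with quantile normalization (0.0537). Of 25 cholesterol synthesis genes 24 were higher and 0 lower, Stard4 first (4.23), with a relative median of 1.76 (adjusted p = 2.92e-06, but adjusted p = 0.384 with an estimated correlation). Of 32 homeostatic astrocyte genes 25 were higher, 15 after median-of-ratios scaling, and Apoe (-2.84) and Cbs (-0.87) lower (adjusted p = 0.00591, but adjusted p = 0.753 with an estimated correlation). Of 13 meningeal fibroblast markers 10 were lower and 0 higher (adjusted p = 4.91e-08, but adjusted p = 0.0816 with an estimated correlation). Adjusted over the list alone, these counts of the interaction were the same.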

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

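The tests of the 3 patterns weighed here were chosen only after the results were seen, except the test on genes with high TPM, while the interaction test was planned.

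The difference between the cultures was not the same at day 5 and day 32 for 9243 genes, by the test of the interaction. Among the genes named by rule, the interaction was positive, a higher change in MGS than in CV, for Rps27 (9.07, with the uncertainty given above), Pcp4 (8.64), Myoc (7.21), Itgb8 (6.28) and Xylt1 (6.19). It was negative for Lcn2 (-10.08), Cd72 (-9.09), Spp1 (-8.62), Lyz2 (-8.23) and C1qb (-8.13). Of the 15 genes fixed beforehand it was also called for Gfap (0.57), Aqp4 (3.12), Slc1a2 (2.80), Slc1a3 (1.43), S100b (2.72), Ctgf (0.55), Serpina3n (-0.72), C3 (-2.93) and Mki67 (1.83). The values of Gfap and Ctgf turned after median-of-ratios scaling (-0.26 and -0.28) and were 0.04 and 0.023 with FPKM, not called, that of Ctgf was 0.15 and not called after the length and GC correction, and that of Mki67 after the length and GC correction (-0.25). Not called were Vim (0.41, limma adjusted p = 0.0623), Aldh1l1 (0.07), Cyr61 (0.27), Ankrd1 (0.51) and Acta2 (0.33). Aldh1l1 was called lower after median-of-ratios scaling (-0.75), with FPKM (-0.45) and after the length and GC correction (-0.57), and Cyr61 after median-of-ratios scaling (-0.56). With quantile normalization Vim (1.59), Cyr61 (0.76), Ankrd1 (0.40) and Acta2 (0.55) were called higher. Vim was also called with robust moderation (0.41), and Ankrd1 at a pseudocount of 5 (0.21), without a filter and with a replicate block (0.51 in both). Without single MGS libraries the calls of Gfap (adjusted p from 0.0672 to 0.0705), Serpina3n (0.0679 to 0.0791), Ctgf (0.0612 to 0.0774) and Rps27 (0.0547 to 0.0584) were lost. The Slc1a3 call was lost without MGS day 5 replicate 1 (0.0554), MGS day 32 replicate 2 (0.0516) or CV day 5 replicate 2 (0.0592), after median-of-ratios scaling (0.0801) and after the length and GC correction (0.0757), the Ctgf call also without CV day 5 replicate 2 (0.0573), and the Serpina3n call also without CV day 5 replicate 1 (0.068). Without CV day 5 replicate 2 the value of Rps27 was 5.57, and without CV day 32 replicate 2 the interactions of Vim, Cyr61, Ankrd1 and Acta2 were called (0.46, 0.43, 0.70 and 0.34), that of Vim also without CV day 5 replicate 2 (0.51). Without CV day 32 replicate 1 Cyr61 was 0.11 and Ankrd1 0.33, not called. Without single CV libraries Aldh1l1 lay between 0.007 and 0.14, not called. Among the gene lists, microglia markers (median -6.42) and class I antigen presentation (median -1.94) were called in the interaction with both correlations. Unless stated otherwise, medians in this section are not set against that of all genes.

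At day 32 the log2 fold change of MGS against CV climbed with transcript length, by 1.52 from the shortest to the longest eighth of genes. Lower depth of the CV libraries as its whole cause is argued against by day 5, where CV was also the shallower culture and the difference was -0.60. Low genes near the floor are argued against by the genes with the highest mean TPM, the top 25%, where it was 1.39. A length dependence that varies between libraries stays open, since the CV libraries of day 32 differed from each other by 0.78 and those of CV at day 5 by 0.38. It may account for part of the climb, but with 2 libraries per culture and day its part and that of a difference between the cultures, the biological explanation, which was not tested, stay open.

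Microglia markers rose in CV between the days, and at day 32 Lyz2 stood at 10316 ± 1222 TPM, C1qb at 1910 ± 211, C1qa at 1507 ± 232 and Tyrobp at 774 ± 131 (n = 2). A lower share of astrocytes in CV at day 32 as the whole cause is argued against by the other cell types, of which the ependymal markers had the highest median change, 1.45, against 6.85 for the microglia markers. Length or GC dependence is argued against by a microglia median of -3.44 for MGS against CV at day 32 after the correction. Within CV, after the same correction, the microglia median lay 6.90 above that of all genes. Microglia in the CV cultures by day 32 are a candidate source, a hypothesis under which other leukocyte genes should rise too. Of 25 on no fixed list 25 rose, against 16% of all genes. Those 25 were chosen after their values were seen, so the count describes these data and is no independent test. Of the 18 markers 1 is also expressed by astrocytes, the labels name no sort or gate, and expression of these genes by astrocytes stays open.

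Meningeal fibroblast markers were higher in MGS at both days, with Ptgds at 7392 and 10514 TPM, Igf2 at 1735 and 879 and Dcn at 843 and 564 at day 5 and day 32. A lower share of astrocytes in MGS stays open as a cause, in part or whole, since markers of other cell types with a mean of at least 5 TPM were higher too. Their median was 2.53 for 53 markers at day 5, against 5.16 for the fibroblast markers (SD over markers 2.50 and 2.78). At day 32 it was 2.31 for 36 markers, without microglia, against 3.34. A lower share alone would lower astrocyte genes. Of 32 homeostatic astrocyte genes 16 were higher and 8 lower in MGS at day 5, which does not decide it. At day 32 26 were higher and 2 lower, or 23 and 4 after median-of-ratios scaling. Within CV 22 of the 32 genes fell between the days, so the counts at day 32 may reflect a fall in CV. They also carry the shift of all genes at that day, and do not decide it either. Length or GC dependence is argued against at day 5 by a fibroblast median of 4.98 after the correction. Meningeal fibroblasts in the MGS cultures are a candidate source, a hypothesis under which other fibroblast genes should be higher at both days. Of 23 on no fixed list 18 were, against 15.6% of all genes. Those 23 were also chosen after their values were seen, so the count is no independent test. Igfbp2 and Ptgds, 2 of the 13, are also expressed by other glia, the labels name no sort or gate, and an effect of MGS on astrocytes stays open. Choroid plexus epithelium was not among the other cell types compared. Of 14 of its genes 13 were higher in MGS and 1 lower at day 5, and 14 were higher at day 32.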

How the results depend on the processing

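The length and GC correction, group weights, the series-wide table and the crossed block were chosen after the results were seen, and the other settings were planned. The counts of genes called stayed within 1.5 times under all settings except the following, whose cause was not tested unless given. A 2-fold threshold, stricter by construction, left 3505 genes at day 5, 5710 at day 32, 2720 within MGS, 3758 within CV and 1397 shared by both days in 1 direction. Within MGS the count was 11874 with group weights and 11596 with only the libraries compared, and within CV 4895 and 3483. The noisy CV libraries of day 32 then no longer set the spread for MGS, whose group weight was 3.086 against 0.152. Nor did the less variable MGS libraries then lower the spread used for CV. With the shared spread 7997 genes were called within CV, so SEs and adjusted p-values there may be too small. The shared count was 5383 after the length and GC correction and 5491 with a replicate block added. Leaving out 1 library, where the lone library of its group is assumed to vary like the other groups, gave 4523 to 10086 genes at day 5, 7431 to 11848 at day 32, 2455 to 9732 within MGS, 4830 to 10676 within CV, 6637 to 11473 in the interaction and 2334 to 4194 shared. Of 165 tests of lists 89 were called, and 78 to 91 under the alternatives. Directions turned for Vim at day 32 (0.25) and Syn1 within MGS (-0.10) with quantile normalization, for Flnc at day 32 (-0.90), for Mki67 (-0.25), Erap1 (-0.054) and Hc (-0.51) in the interaction after the length and GC correction with and without a block, and for Gfap (-0.26) and Ctgf (-0.28) in the interaction after median-of-ratios scaling. For nuclear oxidative phosphorylation in the interaction the relative median was -0.008 with quantile normalization and turned to 0.026 after the length and GC correction with and without a block. Values not called turned and were called for Aldh1l1 in the interaction after median-of-ratios scaling (-0.75), with FPKM (-0.45) and after the length and GC correction with and without a block (-0.57), and for Cyr61 in the interaction after median-of-ratios scaling (-0.56). The same held for Mki67 at day 32 after median-of-ratios scaling (-0.39), quantile normalization (-0.50) and the length and GC correction with and without a block (-1.39), and for Aqp4 at day 5 after that correction with a block (0.36). With quantile normalization the homeostatic astrocyte list within MGS, not called, turned in its test and was called (0.38). The cause was not tested. Quantile normalization kept direction and call for 138 of the 165 tests of lists, with 18 calls lost and 7 gained, the length and GC correction for 150, median-of-ratios scaling for 159, and FPKM for 160. Of 250 gene values these settings kept 236, 237, 234 and 242, and leaving out single libraries kept 231 to 247.

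The replicate numbers were not taken to pair the libraries, since the labels name no shared culture or batch and the deviations of libraries with the same number correlated above 0.1 in only some pairs of groups. The values of r were 0.444 between the CV groups, 0.175 between MGS day 5 and CV day 32, and 0.091, -0.131, -0.057 and -0.062 for the others, so a pairing within CV stays open. In both CV groups replicate 2 minus replicate 1 rose with transcript length, by 0.38 at day 5 and 0.78 at day 32. Such a shared trend may give part of the r between the CV groups, which was not tested. With the number as a replicate block 7894 genes were called at day 5, 10440 at day 32, 7209 within MGS, 8529 within CV and 9568 in the interaction, 3384 were shared, and 86 tests of lists were called. With a block within day the counts were 6961, 9760, 6017, 7647, 8768 and 3013. With the numbers of MGS at day 32 crossed, 7365 genes were called within MGS. At day 32 the block ended the list calls of complement (adjusted p = 0.058), immediate early genes (0.0533) and stress and unfolded protein response (0.05). Depth is known only as aligned bases, lowest in CV at day 32, where changes of low genes are the least certain.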

Other observations

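The 3 gene lists here were chosen after the results were seen, from a scan of the genes with the largest changes, so their counts and medians describe these data and no test of a list is given. Of 14 measured genes of choroid plexus epithelium, the cells that make cerebrospinal fluid, 13 were higher in MGS at day 5, and Otx2 was lower (-0.90), with a median 2.60 above that of all genes. At day 32 all 14 were higher (relative median 2.35). The thyroxine carrier gene Ttr had log2 fold changes of 7.08 and 4.68 at the 2 days, the anion transporter gene Slc13a4 5.95 and 5.91, the water channel gene Aqp1 4.76 and 3.72, and the potassium channel gene Kcnj13 4.61 and 4.02. From day 5 to day 32, 5 of the 14 fell in MGS, Ttr among them (-2.95), and 1 rose, while within CV 1 rose and 5 fell. In the interaction 2 were higher and 3 lower.

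Of 21 measured genes of the axoneme, the dyneins, radial spokes and tektins of motile cilia, 16 were higher and 1 lower in MGS at day 5 (relative median 1.38) and 21 were higher at day 32 (relative median 2.68). Within MGS 19 rose and 0 fell between the days (relative median 1.59), and within CV 7 rose and 2 fell. In the interaction 15 were higher and 0 lower. The ependymal markers share Rsph1 and Dnahc11 with this list. Of 20 imprinted genes 8 were higher and 6 lower at day 5, and 16 higher and 2 lower at day 32. H19 had log2 fold changes of 6.76 and 5.38 at the 2 days, Igf2 6.07 and 4.08, Nnat 3.78 and 5.90, and Mest -3.51 and -1.86. Igf2 is also among the meningeal fibroblast markers. Between the days 6 imprinted genes rose and 5 fell in MGS, and 4 rose and 13 fell in CV, with 11 higher and 4 lower in the interaction.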
